A study of Homo sapiens with 10 samples.

How the data were processed

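The data are RNA sequencing libraries of H9 cells in 5 groups with 2 biological replicates each, prepared with a stranded mRNA kit per the labels' protocols. The deposited table holds counts of reads per gene symbol, not normalized by the authors: its values are whole numbers whose sums run from 17.3 to 84.2 M per library. GRCh38 and DESeq2 are named in the submitters' processing notes, without a version or a role, and the counting program named for the table is Rsubread. The aligner, read filters, strand setting and handling of reads that match several genes are not given in the sources used here. Strand handling being unknown, genes overlapping on opposite strands are uncertain. A deposited annotation of GRCh38 (Ensembl release 84) gave other values, namely gene starts and ends: 16850 of the 17307 genes matched it by symbol, and TBXT, under another symbol there, has no position here. A GENCODE release matched 17224 genes and gave gene type, GC content and shared sequence. Repeated gene symbols numbered 49, 47 genes had 0 counts in all libraries, and 0 mitochondrial genes were present in the table.

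Depth limits the low genes first. In the shallowest library, E24 replicate 2 with 17.3 M counts, 3 counts correspond to a level far below 1 CPM, and over both E24 libraries the floor of 3 counts is 0.0556 CPM. Intervals for genes with 1 to 3 counts in a group are exact and cover counting error only. Replicates of each group had log CPM correlations of 0.982 to 0.990 across genes and differed by more than sampling noise, with a chi-square of 31.6 to 72.5 per gene, so no pair was one library deposited 2 times. With 2 libraries per group, p-values measure the spread between these cultures.

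Choices of groups, tests, the gene lists and the rule for named genes were made before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, glmQLFit with robust estimation and glmQLFTest), with all 10 libraries and 5 residual degrees of freedom in one fit, since 2 libraries per group give a poor estimate of the spread alone. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The SE of a log2 fold change is its size divided by the square root of F. The comparisons were E24 and E24woTET against UD, E24RO against E24, E24TET against E24woTET, the difference between those last 2 effects, and E24woTET against E24. Levels are CPM computed from the deposited counts over TMM-scaled library totals, without a pseudocount.

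Of 33 fixed gene lists, 32 had at least 5 tested genes. Some lists share members, so their results are not separate. The streak list shares TBXT, SP5, DKK1, WNT3, WNT8A, CDX1 and CDX2 with the WNT target list. It shares NODAL, LEFTY1, LEFTY2, CER1, FOXH1, EOMES, GSC, MIXL1, LHX1, FGF8 and WNT3 with the NODAL and activin target list. Each was tested with camera (limma 3.58.1), which asks whether a list moves relative to other genes, with a preset correlation of 0.01 and then an estimated one, adjusted over the lists of a comparison. With an estimated correlation none of the fixed lists printed here kept its call in any comparison. Named genes are the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those called, with at least 5 CPM in a group and separate libraries, up to 4 genes with the smallest adjusted p of each fixed list, and 14 genes named whatever their values. Those 14 are CDK1, CCNB1, POU5F1, NANOG, SOX2, TBXT, MIXL1, EOMES, GSC, SOX17, FOXA2, CXCR4, HAND1 and CDKN1A. Of them 5 rose, 3 fell and 6 did not pass in E24 against UD, 1, 4 and 9 in E24RO against E24, 0, 1 and 13 in E24TET against E24woTET, 1, 1 and 12 in the difference of those 2, 1, 0 and 13 in E24woTET against E24, and 7, 3 and 4 in E24woTET against UD. The text names the genes that matter and summarises the rest, and some genes that met the rule are not reported here.

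Shared sequence is the percent of a gene's 50-mers (1 in 4 sampled) found in another gene. Chromosome medians were planned over whole chromosomes, and the arm and the region used in the text were set after the data were seen. The alternatives were RLE size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, only the groups compared, the replicate number as a block and each library left out in turn. Leaving out genes sharing over 5% of their 50-mers, taking out a GC trend per library (lowess span 0.3), and both together were added after the data were seen. A left-out library leaves its group with 1 library, which is then assumed to vary like the other groups. No scaling alternative moved the median of all genes by 0.1 or more on the log2 scale. Each method sets the typical gene near 0, so this is no check of the scaling. The test was checked on simulated counts, drawn independently per gene with the fitted spread, in which 66 or 67 of 15465 genes changed by each fold. For E24 against UD 10.4%, 52.2% and 84.8% of genes changed 1.5-, 2- and 4-fold were called. The same shares were 5.97%, 37.3% and 75.8% for E24RO against E24 and 5.97%, 37.3% and 81.8% for E24woTET against E24. False calls in the 3 runs numbered 6, 7 and 1. A simulated GC trend in UD gave 1051 calls without the GC correction and 1 with it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.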

Results

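RNA sequencing of H9 cells, a human embryonic stem cell line, covers 5 groups of 2 biological replicates. It bears on how the mitotic kinase CDK1 acts in the exit from pluripotency towards mesendoderm. Undifferentiated cells are called UD. The other groups were collected after 24 h in a mesendoderm medium with activin A, BMP, the PI3K inhibitor LY294002 and the GSK3 inhibitor CHIR99021, after release from a nocodazole block. They are cells not labelled with an shRNA, called parental here (E24), parental cells given the CDK1 inhibitor RO3306, from 8 to 24 h by the sample titles (E24RO), and cells carrying a tetracycline-inducible shRNA against CDK1 without (E24woTET) or with tetracycline (E24TET). The labels do not say whether UD was blocked in nocodazole, or whether UD and E24 came from the same stock of H9 cells. Total counts were 68.7 and 84.2 M in UD, 33.1 and 17.3 M in E24, 19.3 and 36.2 M in E24RO, 30.4 and 31.5 M in E24woTET and 35.3 and 33.3 M in E24TET. Of 17307 genes in the table, 15465 were tested. Levels are given in CPM as mean ± SD with n = 2 libraries per group. Changes are given as log2 fold changes ± SE from the edgeR quasi-likelihood fit over all 10 libraries with Benjamini-Hochberg adjusted p. The 95% interval of a gene's log2 fold change reached a median of about 0.47 to either side of the estimate, and of 0.659 for the difference between inhibitor and knockdown effects. Intervals cover these 2 cultures per group only.

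CDK1 (GRCh38 chromosome 10, 60778331 to 60794852) is the gene targeted by the shRNA. Its level was 65.6 and 63.5 CPM in the UD libraries, 138 and 154 in E24, 160.0 and 124 in E24RO, 129 and 133 in E24woTET, and 52.3 and 48.9 in E24TET. With tetracycline its log2 fold change was -1.37 ± 0.14, adjusted p = 0.0409, a fall of 2.59-fold in the direction of the labels. The inhibitor, which acts on the kinase and not on its mRNA, left no detectable change (-0.04 ± 0.14, adjusted p = 0.863). CDK1 was higher in E24 than in UD (1.18 ± 0.14, adjusted p = 7.83e-05), by 0.47 when the GC trend of the libraries was taken out.

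**Figure D1:**
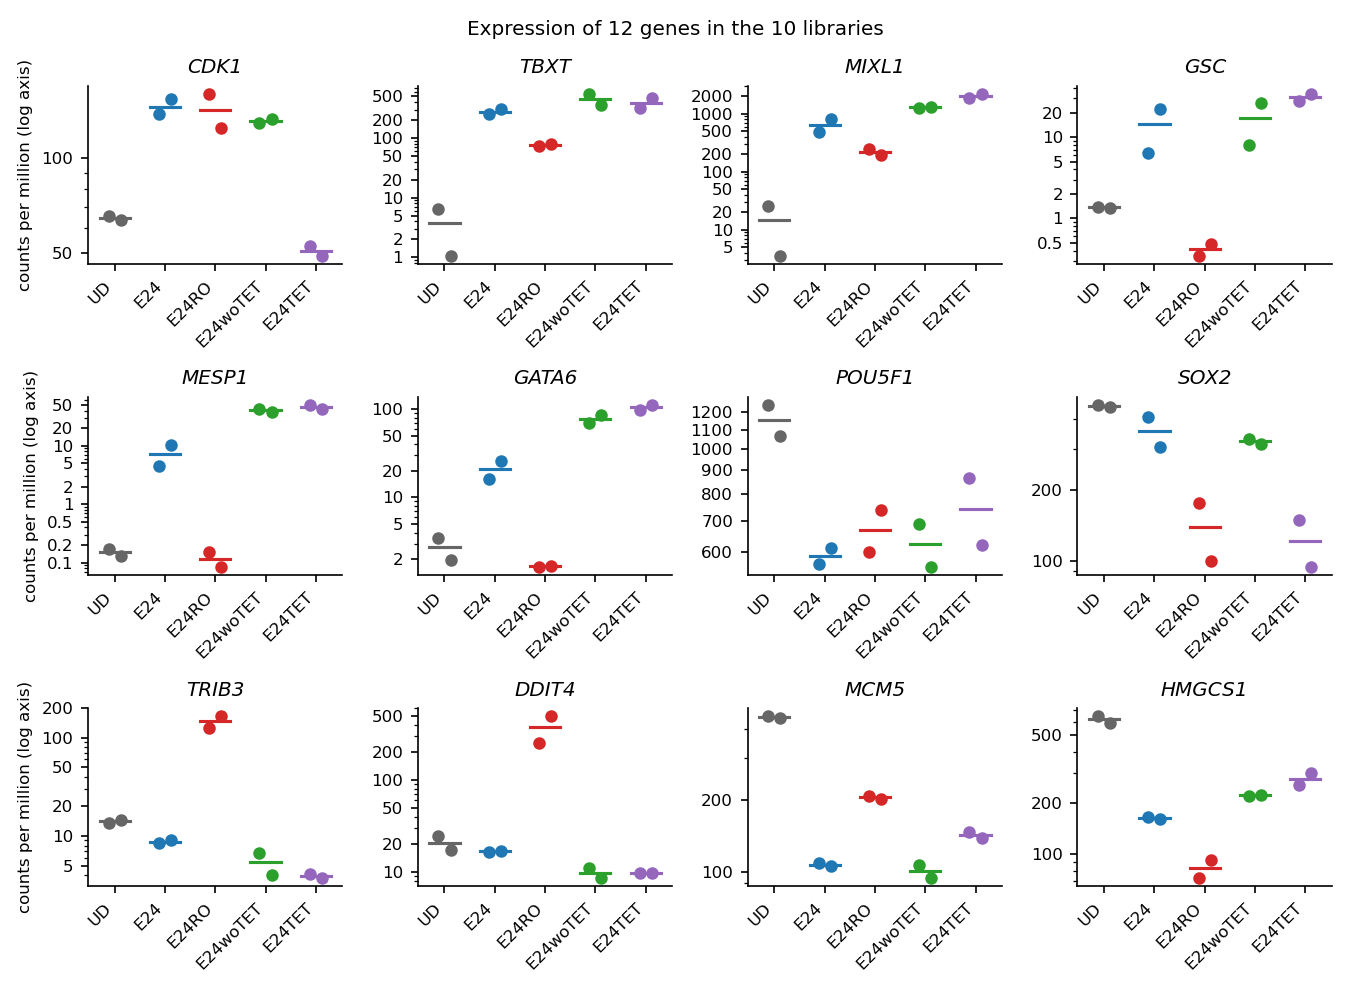
Expression of 12 genes in CPM (log axis) in each library, by group, with a bar at the group mean. CDK1 is lowest in E24TET, MESP1, GSC and GATA6 are lowest in E24RO or UD, and TRIB3 and DDIT4 are highest in E24RO.

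Exit from pluripotency towards mesendoderm was measured by E24 against UD. TBXT, the T-box factor of the primitive streak, went from 3.77 ± 3.82 to 279 ± 41.7 CPM (6.23 ± 0.69, adjusted p = 4.98e-05). MIXL1, a homeobox factor of the streak (chromosome 1, 226223618 to 226227054), went from 14.6 ± 15.6 to 649.5 ± 226 CPM (5.48 ± 0.76, adjusted p = 0.000185). EVX1, another streak homeobox gene, rose by 6.63 ± 0.41 and MESP1, a factor of nascent mesoderm (chromosome 15, 89748661 to 89751310), by 5.56 ± 0.43. EOMES and GSC, factors of the anterior streak, rose by 3.98 ± 0.93 and 3.37 ± 0.64. The size of these rises depended on single libraries: EOMES was 6.96 without UD replicate 1 and GSC 2.23 without E24 replicate 2. TBXT was 5.42 without UD replicate 2 and 8.01 without UD replicate 1, and MIXL1 was 4.65 and 7.48. In the list of primitive streak and mesendoderm genes, 17 rose and 1 fell of 24 tested members (18 and 1 adjusted over the list alone). The streak list had a median of 3.40 (adjusted p = 0.000185, and adjusted p = 0.479 with an estimated correlation), of 2.91 without UD replicate 2 and of 4.26 without UD replicate 1. WNT targets, a list that shares TBXT, SP5, DKK1 and other members with the streak list, moved the same way. Of 25 tested members, 18 rose and 1 fell (18 and 1 adjusted over the list alone). The WNT target list had a median of 1.63 (adjusted p = 0.000214, and adjusted p = 0.479 with an estimated correlation). Examples are SP5 (3.44 ± 0.19), the secreted inhibitors DKK1 (5.59 ± 0.55) and NOTUM (5.00 ± 0.46) and the receptor ligase RNF43 (3.73 ± 0.20).

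Pluripotency genes fell in part. POU5F1, which encodes OCT4, fell from 1154 ± 126 to 588 ± 31.3 CPM (-0.97 ± 0.19, adjusted p = 0.00154). LIN28A (-1.26 ± 0.13), ZFP42 (-2.73 ± 0.21) and PRDM14 (-2.90 ± 0.34) fell too. NANOG (-0.24 ± 0.40, adjusted p = 0.624) and SOX2 (-0.35 ± 0.28, adjusted p = 0.292) did not pass the test. SOX2 was -0.58 without E24 replicate 1 and -0.16 without E24 replicate 2, and NANOG 0.38 without UD replicate 1, -0.69 without UD replicate 2, 0.03 without E24 replicate 1 and -0.57 without E24 replicate 2. Of the pluripotency list, 1 rose and 14 fell of 25 tested members (1 and 14 adjusted over the list alone). The pluripotency list had a median of -0.92 (adjusted p = 0.00445, and adjusted p = 0.625 with an estimated correlation). Of its members, 5 share over 5% of their sequence with another gene. Genes sharing over 5 to 20% had a median of -0.08 in E24 against UD, but those sharing more were lower in UD, as given below. The shares of POU5F1 and NANOG are not given here, so a fall from UD in either may be understated. In the neuroectoderm list, 1 rose and 19 fell of 22 tested members (1 and 19 adjusted over the list alone). The neuroectoderm list had a median of -2.33 (adjusted p = 0.000228, and adjusted p = 0.479 with an estimated correlation), and of -3.89 without E24 replicate 1. PAX6, a factor of the neural tube, fell by 3.52 ± 0.35 on the log2 scale and FABP7, a marker of radial glia, fell by 3.60 ± 0.32. The fibroblast list was also lower (0 rose and 11 fell of 14 tested members, 0 and 11 adjusted over the list alone), among them the collagen gene COL3A1 (-6.84 ± 0.45) and TAGLN (-3.12 ± 0.33). The fibroblast list had a median of -2.08 (adjusted p = 0.00199, and adjusted p = 0.479 with an estimated correlation). Among neural crest genes, 0 rose and 10 fell of 14 tested members (0 and 10 adjusted over the list alone). The neural crest list had a median of -1.77 (adjusted p = 0.0251, and adjusted p = 0.479 with an estimated correlation).

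Genes of G1/S and DNA replication were lower after 24 h: 0 rose and 24 fell of 30 tested members (0 and 24 adjusted over the list alone). The G1/S list had a median of -0.83 (adjusted p = 1.52e-05, and adjusted p = 0.479 with an estimated correlation). The replicative helicase genes MCM5 (-2.06 ± 0.12) and MCM2 (-1.54 ± 0.13) and the cyclin gene CCNE1 (-1.72 ± 0.15) are examples. The list of G2/M and mitosis genes went both ways, with 9 rose and 14 fell of 40 tested members (9 and 13 adjusted over the list alone) and an adjusted p of 0.654 for the list. The kinetochore motor gene CENPE rose (2.29 ± 0.17, and 1.43 with the GC trend taken out) and the mitotic transcription factor gene FOXM1 fell (-1.70 ± 0.13). Definitive endoderm (5 rose and 8 fell of 22 tested members, 5 and 8 adjusted over the list alone, adjusted p = 0.629) and mesoderm genes (3 rose and 6 fell of 22 tested members, 3 and 6 adjusted over the list alone, adjusted p = 0.550) had no list change past the threshold. The sterol synthesis list did not pass but lay close to the threshold (3 rose and 10 fell of 24 tested members, 3 and 10 adjusted over the list alone, median -0.29, adjusted p = 0.0575, and adjusted p = 0.838 with an estimated correlation). It passed with DESeq2 (adjusted p = 0.0339), with no filter on low counts (0.0443), without UD replicate 1 (0.0446), UD replicate 2 (0.0445) or E24 replicate 2 (0.0288), without genes sharing sequence (0.0199), and with the GC trend taken out (0.0382, or 0.0131 with both). Its median was -0.14 without E24 replicate 1 and -0.44 without E24 replicate 2. Its members FDFT1 (-1.87 ± 0.12), in the first 13 Mb of chromosome 8, and HMGCS1 (-1.93 ± 0.15), enzymes of the cholesterol pathway, fell.

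In all, 4863 genes were higher and 4636 lower in E24 than in UD, 3197 and 2661 of them by at least 2-fold. Genes near-identical in sequence to another gene were far lower in UD than in any 24 h library, which enters this count. Over the 123 genes sharing more than 80% of their 50-mers, the median log2 fold change was 5.27, with RGPD8 (11.01) and EIF3CL (10.27) at the top. The median was 2.83 over the 105 genes sharing over 50 to 80% (95 higher and 3 lower) and 0.71 over the 199 genes sharing over 20 to 50%. Single members of such families are uncertain here. Genes under 40% GC had a median of 0.63 and genes over 60% GC of -0.35.

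**Figure D2:**
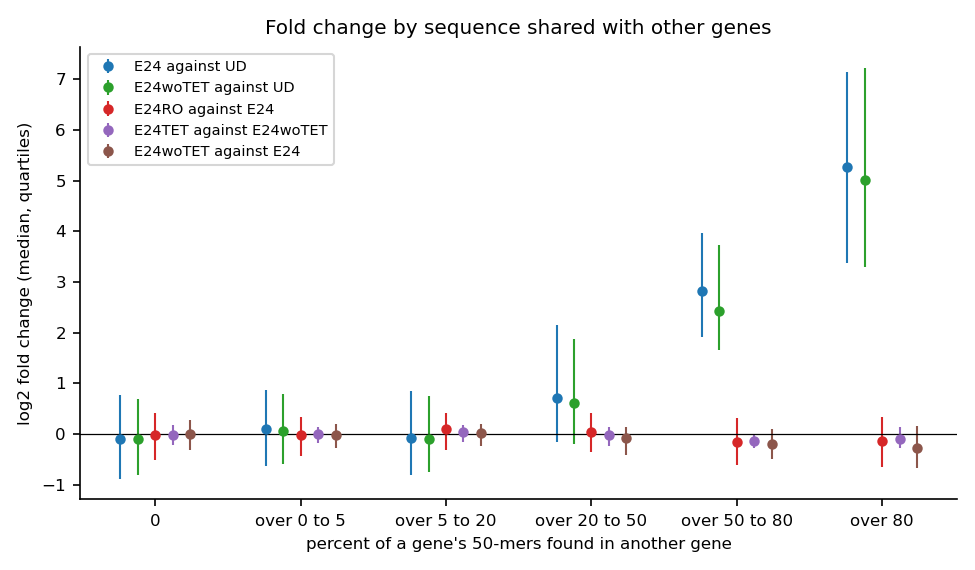
Median log2 fold change with quartiles (vertical axis) by the percent of a gene's 50-mers found in another gene (horizontal axis), for comparisons with and without UD. Genes sharing more than 80% have a median of 5.27 in E24 against UD and of -0.14 in E24RO against E24.

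The shRNA line without tetracycline was compared with UD in the same way. UD is not labelled as the line, so this comparison mixes differentiation with differences of the line. Protein-coding genes of the long arm of chromosome 1 had a median log2 fold change of 0.53 here and of 0.09 in E24 against UD. Streak genes were higher (21 rose and 1 fell of 24 tested members, 21 and 1 adjusted over the list alone), with TBXT at 6.94 ± 0.71, MIXL1 at 6.48 ± 0.79, EVX1 at 8.07 ± 0.44 and MESP1 at 8.05 ± 0.44. The streak list had a median of 3.92 (adjusted p = 4.42e-08, and adjusted p = 0.493 with an estimated correlation). Without UD replicate 2 TBXT was 6.15, MIXL1 5.67 and the streak median 3.38, and without UD replicate 1 they were 8.72, 8.49 and 5.23. MSGN1, a factor of presomitic mesoderm, had 2 counts over both UD libraries and 1183 in E24woTET, a ratio of 1337 with a 95% counting interval of 369 to 11056. WNT targets rose (19 rose and 1 fell of 25 tested members, 19 and 1 adjusted over the list alone). The WNT target list had a median of 2.88 (adjusted p = 3.65e-07, and adjusted p = 0.493 with an estimated correlation). G1/S genes fell (0 rose and 24 fell of 30 tested members, 0 and 24 adjusted over the list alone). The G1/S list had a median of -0.87 (adjusted p = 2.32e-06, and adjusted p = 0.493 with an estimated correlation). Neuroectoderm genes fell (1 rose and 19 fell of 22 tested members, 1 and 19 adjusted over the list alone). The neuroectoderm list had a median of -2.73 (adjusted p = 1.53e-05, and adjusted p = 0.493 with an estimated correlation). Pluripotency genes fell too (1 rose and 17 fell of 25 tested members, 1 and 17 adjusted over the list alone). The pluripotency list had a median of -0.99 (adjusted p = 0.000256, and adjusted p = 0.705 with an estimated correlation). As in E24 against UD, falls of members that share sequence with other genes may be understated. Among mesoderm genes, 12 rose and 6 fell of 22 tested members (12 and 6 adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.558). In total 4599 genes were higher and 4550 lower. Of the 123 genes sharing more than 80% of their 50-mers with another gene, 116 were among the higher ones.

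Inhibition of CDK1 during differentiation was measured by E24RO against E24, both in parental cells. MESP1 fell from 7.36 ± 3.99 to 0.118 ± 0.0452 CPM (-6.00 ± 0.53, adjusted p = 0.000326). GSC (chromosome 14, 94768216 to 94770230), an organizer homeobox gene, went from 14.3 ± 11.2 to 0.417 ± 0.0962 CPM (-5.02 ± 0.78, adjusted p = 0.00276). GATA6, a mesendoderm zinc finger factor, had a log2 fold change of -3.66 ± 0.33. The apelin receptor gene APLNR (-4.61 ± 0.63), the VEGF receptor gene KDR (-3.20 ± 0.23) and the secreted WNT inhibitor gene DKK4 (-5.37 ± 0.81) fell too. In the streak and mesendoderm list, 0 rose and 13 fell of 24 tested members (0 and 13 adjusted over the list alone). The streak list had a median of -1.53 (adjusted p = 5.23e-06, and adjusted p = 0.387 with an estimated correlation). TBXT was at 77.2 ± 3.40 CPM (-1.85 ± 0.56, adjusted p = 0.0358). That call was lost in each fit that left out 1 E24 or E24RO library, at values from -1.99 to -1.69. It was also lost with no filter on low counts (adjusted p = 0.0539) and with the replicate block (adjusted p = 0.0664). MIXL1 (-1.57 ± 0.64, adjusted p = 0.0918) and EOMES (-0.73 ± 0.82, adjusted p = 0.541) did not pass, and EOMES was -0.25 without E24 replicate 2, -0.39 without E24RO replicate 1 and -1.17 without E24RO replicate 2. NODAL and activin targets were lower as a list (2 rose and 8 fell of 24 tested members, 2 and 8 adjusted over the list alone). That list shares GSC, MIXL1, EOMES and other members with the streak list. The NODAL and activin target list had a median of -0.38 (adjusted p = 0.0154, and adjusted p = 0.646 with an estimated correlation). Its median was -0.69 without E24 replicate 1 and -0.79 without E24RO replicate 2. The call was lost without E24RO replicate 1 (median -0.39) and without genes sharing sequence (median -0.36, adjusted p = 0.0555). Mesoderm genes went both ways (5 rose and 5 fell of 22 tested members, 6 and 5 adjusted over the list alone). As a list they had a median of 0.30 and did not pass (adjusted p = 0.768). HAND1 rose, with 3 counts over both E24 libraries and 24 in E24RO. That is a ratio of 7.83 with a 95% counting interval of 2.38 to 40.6. Its log2 fold change was 1.96 without E24 replicate 1, where its call was lost, and 3.83 without E24 replicate 2. Definitive endoderm genes did not pass as a list (1 rose and 5 fell of 22 tested members, 1 and 5 adjusted over the list alone, median -0.46, adjusted p = 0.191). Without E24 replicate 1 the list passed (adjusted p = 0.0359), with a median of -0.25.

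The pluripotency list was lower with the inhibitor as well: 2 rose and 11 fell of 25 tested members (2 and 11 adjusted over the list alone). The pluripotency list had a median of -0.60 (adjusted p = 0.00223, and adjusted p = 0.570 with an estimated correlation). SOX2 (-1.37 ± 0.28, adjusted p = 0.00787) and the de novo DNA methyltransferase gene DNMT3B (-1.25 ± 0.20) fell. POU5F1 (0.19 ± 0.19, adjusted p = 0.495) and NANOG (-0.14 ± 0.40, adjusted p = 0.826, from -0.72 without E24RO replicate 2 to 0.27 without E24RO replicate 1) did not pass. SP8, a zinc finger factor of the early embryo, fell from 75.9 ± 1.20 to 17.9 ± 0.394 CPM (-2.08 ± 0.12, adjusted p = 7.76e-05).

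Genes of the ATF4 and integrated stress response rose with the inhibitor: 23 rose and 0 fell of 25 tested members (24 and 0 adjusted over the list alone). The ATF4 list had a median of 1.75 (adjusted p = 3.19e-32, and adjusted p = 0.380 with an estimated correlation). TRIB3 (chromosome 20, 362835 to 397559), a pseudokinase induced by ATF4, went from 8.72 ± 0.411 to 146 ± 27.9 CPM (4.07 ± 0.24, adjusted p = 7.76e-05). DDIT4 (chromosome 10, 72273920 to 72276036), an inhibitor of mTORC1 signalling, went from 16.7 ± 0.0747 to 375 ± 169.6 CPM (4.48 ± 0.32, adjusted p = 0.000166). SESN2 (2.89 ± 0.23), ATF3 (2.68 ± 0.28) and CEBPB (2.23 ± 0.17), a further set of stress-induced genes, rose too. Heat shock and unfolded protein genes rose (12 rose and 2 fell of 21 tested members, 13 and 2 adjusted over the list alone), among them HERPUD1 (2.25 ± 0.24), a component of endoplasmic reticulum protein degradation. The heat shock list had a median of 0.59 (adjusted p = 0.000314, and adjusted p = 0.387 with an estimated correlation). Without genes sharing sequence its median was 0.35 (adjusted p = 0.0555). Among p53 targets, 10 rose and 1 fell of 30 tested members (10 and 1 adjusted over the list alone). The p53 target list had a median of 0.45 (adjusted p = 2.44e-05, and adjusted p = 0.646 with an estimated correlation). It was 0.14 without E24 replicate 2 and 1.00 without E24 replicate 1. GDF15, a stress cytokine gene, rose by 3.51 ± 0.50 and the BH3-only gene BBC3 by 1.77 ± 0.25, while CDKN1A, which encodes the CDK inhibitor p21, did not pass (0.77 ± 0.40, adjusted p = 0.173). The value for CDKN1A was 1.73 without E24 replicate 1 (adjusted p = 0.0127) and 0.23 without E24 replicate 2.

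BMP targets rose (10 rose and 0 fell of 24 tested members, 12 and 0 adjusted over the list alone), among them ID4 (1.53 ± 0.19), MSX2 (1.60 ± 0.23) and the BMP antagonist gene NOG (2.21 ± 0.38). The BMP target list had a median of 1.10 (adjusted p = 2.72e-05, and adjusted p = 0.387 with an estimated correlation). Sterol synthesis genes fell (0 rose and 11 fell of 24 tested members, 0 and 13 adjusted over the list alone). The sterol synthesis list had a median of -0.70 (adjusted p = 7.26e-06, and adjusted p = 0.387 with an estimated correlation). HMGCS1 went from 162 ± 2.63 to 82.7 ± 14.0 CPM (-0.97 ± 0.15), and FDFT1 (-0.91 ± 0.12) fell too. Cytosolic ribosomal protein genes were higher (14 rose and 0 fell of 34 tested members, 19 and 0 adjusted over the list alone), and 16 of them share over 5% of their 50-mers with other genes. The ribosomal protein list had a median of 0.35 (adjusted p = 0.000106, and adjusted p = 0.646 with an estimated correlation). Without E24RO replicate 1 its median was 0.21. G1/S genes rose (12 rose and 1 fell of 30 tested members, 13 and 1 adjusted over the list alone), as MCM5 (0.94 ± 0.12) and the replication licensing gene CDC6 (1.01 ± 0.16) show. The G1/S list had a median of 0.41 (adjusted p = 0.000225, and adjusted p = 0.387 with an estimated correlation). The G2/M and mitosis list was slightly lower (1 rose and 13 fell of 40 tested members, 2 and 13 adjusted over the list alone), with the checkpoint kinase gene BUB1 at -1.06 ± 0.14, the mitotic kinesin gene KIF14 at -1.12 ± 0.15 and CENPE at -0.92 ± 0.16. The G2/M list had a median of -0.21 (adjusted p = 0.0146, and adjusted p = 0.646 with an estimated correlation). Its median was -0.39 without E24RO replicate 1 and -0.03 without E24RO replicate 2 (adjusted p = 0.304).

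With the inhibitor 2132 genes were higher and 2209 lower, 714 and 1158 of them by at least 2-fold. Left-out libraries gave 635 and 837 without E24 replicate 2, 1419 higher without E24 replicate 1, and 1418 lower without E24RO replicate 2. Genes called at least 2-fold higher in E24woTET than in UD formed a set made without the E24 and E24RO libraries. They had a median log2 fold change of -0.33 with the inhibitor (2963 genes, 180 rose and 768 fell, p = 2.69e-08, and p = 0.0652 with an estimated correlation). Those called at least 2-fold lower had a median of 0.21 (2453 genes, 552 rose and 192 fell, p = 5.92e-05, and p = 0.0582 with an estimated correlation), and of 0.34 without E24 replicate 1. UD is not labelled as the shRNA line, so both sets mix differentiation with differences of the line.

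Knockdown of CDK1 during differentiation was measured by E24TET against E24woTET. SOX2 was at 323 ± 10.9 CPM without tetracycline and 121 ± 38.5 CPM with it. The difference did not pass (-1.41 ± 0.28, adjusted p = 0.389, and adjusted p = 0.000963 with DESeq2). TBXT (-0.21 ± 0.54, adjusted p = 0.943), MIXL1 (0.64 ± 0.62, adjusted p = 0.827), EOMES (0.75 ± 0.82, adjusted p = 0.845), GSC (0.84 ± 0.57, adjusted p = 0.746), POU5F1 (0.25 ± 0.19, adjusted p = 0.774) and NANOG (0.09 ± 0.41, adjusted p = 0.972) did not pass either, nor did CDKN1A (0.99 ± 0.40, adjusted p = 0.599). Values with 1 library left out ran from -0.48 to 0.12 for TBXT, -0.0076 to 0.47 for POU5F1 and -0.27 to 0.37 for NANOG. GSC was 0.22 without E24woTET replicate 1 and 1.95 without E24woTET replicate 2. SLITRK5, a neuronal membrane protein gene (-1.55 ± 0.19, adjusted p = 0.0735), SP8 (-0.92 ± 0.12, adjusted p = 0.0735) and PRICKLE1, a planar cell polarity gene (-0.97 ± 0.14, adjusted p = 0.166), were each chosen after its values were seen, and did not pass in the edgeR fit with the groups as the only factor and the filter on low counts. SLITRK5 passed with no filter on low counts (adjusted p = 0.0451), and SLITRK5 and SP8 passed with the replicate block (adjusted p = 0.0493 each). Levels of these genes were 30.8 ± 1.53, 75.9 ± 1.20 and 46.7 ± 3.41 CPM in E24 and 4.85 ± 1.74, 17.9 ± 0.394 and 6.87 ± 1.00 CPM in E24RO. With DESeq2 the adjusted p was 2.43e-11 for SLITRK5, 1.95e-09 for SP8 and 1.23e-06 for PRICKLE1.

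CDK1 was the only gene below the threshold in the edgeR fit with the groups as the only factor and the filter on low counts, with 0 genes higher and 1 lower. With no filter 2 were lower, and with the replicate block 4 were lower. At an unadjusted p under 0.05 there were 1198 genes where chance gives 773, and DESeq2 called 42 higher and 55 lower. The CDK1 call was lost in each fit that left out 1 library, at a log2 fold change between -1.42 and -1.33. It was also lost when the GC trend was taken out, at -1.34 (adjusted p = 0.0671). No group received tetracycline without the shRNA, so an effect of tetracycline itself was not separated. In simulated data for this comparison, 80.3% of genes changed 4-fold, 46.3% of those changed 2-fold and 5.97% of those changed 1.5-fold were called, with 6 false calls. The simulated genes varied independently with the fitted spread, and few were changed, so these shares may not hold for the real libraries.

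As a list, p53 targets were higher with the knockdown (0 rose and 0 fell of 30 tested members, 0 and 0 adjusted over the list alone). The p53 target list had a median of 0.37 (adjusted p = 3.49e-08, and adjusted p = 0.828 with an estimated correlation). G1/S genes were higher too (0 rose and 0 fell of 30 tested members, 3 and 0 adjusted over the list alone). The G1/S list had a median of 0.21 (adjusted p = 4.86e-08, and adjusted p = 0.788 with an estimated correlation). WNT targets were lower (0 rose and 0 fell of 25 tested members, 0 and 2 adjusted over the list alone). The WNT target list had a median of -0.25 (adjusted p = 0.000543, and adjusted p = 0.828 with an estimated correlation). It was 0.0053 without E24TET replicate 1 (adjusted p = 0.309) and -0.70 without E24TET replicate 2. NODAL and activin targets were higher (0 rose and 0 fell of 24 tested members, 0 and 0 adjusted over the list alone). The NODAL and activin target list had a median of 0.45 (adjusted p = 0.00970, and adjusted p = 0.828 with an estimated correlation). Without E24TET replicate 2 it was 0.26 (adjusted p = 0.145). The lists of G2/M and mitosis (median -0.12, adjusted p = 0.0705), ATF4 (median -0.21, adjusted p = 0.122) and streak genes (median 0.24, adjusted p = 0.708) did not pass, with 0 members called in each. The G2/M list passed with DESeq2 (adjusted p = 0.0304) and without E24woTET replicate 1 (adjusted p = 0.0303). The streak median was 0.39 without E24TET replicate 1 and 0.12 without genes sharing sequence. The ATF4 median changed sign, to 0.0699, without E24woTET replicate 1, and was -0.40 (adjusted p = 1.24e-07) without E24woTET replicate 2 and -0.37 (adjusted p = 0.00167) without E24TET replicate 1. Genes at least 2-fold higher in E24 than in UD had a median of -0.16 with the knockdown (3197 genes, p = 1.55e-08, and p = 0.0388 with an estimated correlation). Those at least 2-fold lower had a median of 0.11 (2661 genes, p = 6.63e-07, and p = 0.0816 with an estimated correlation).

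**Figure D3:**
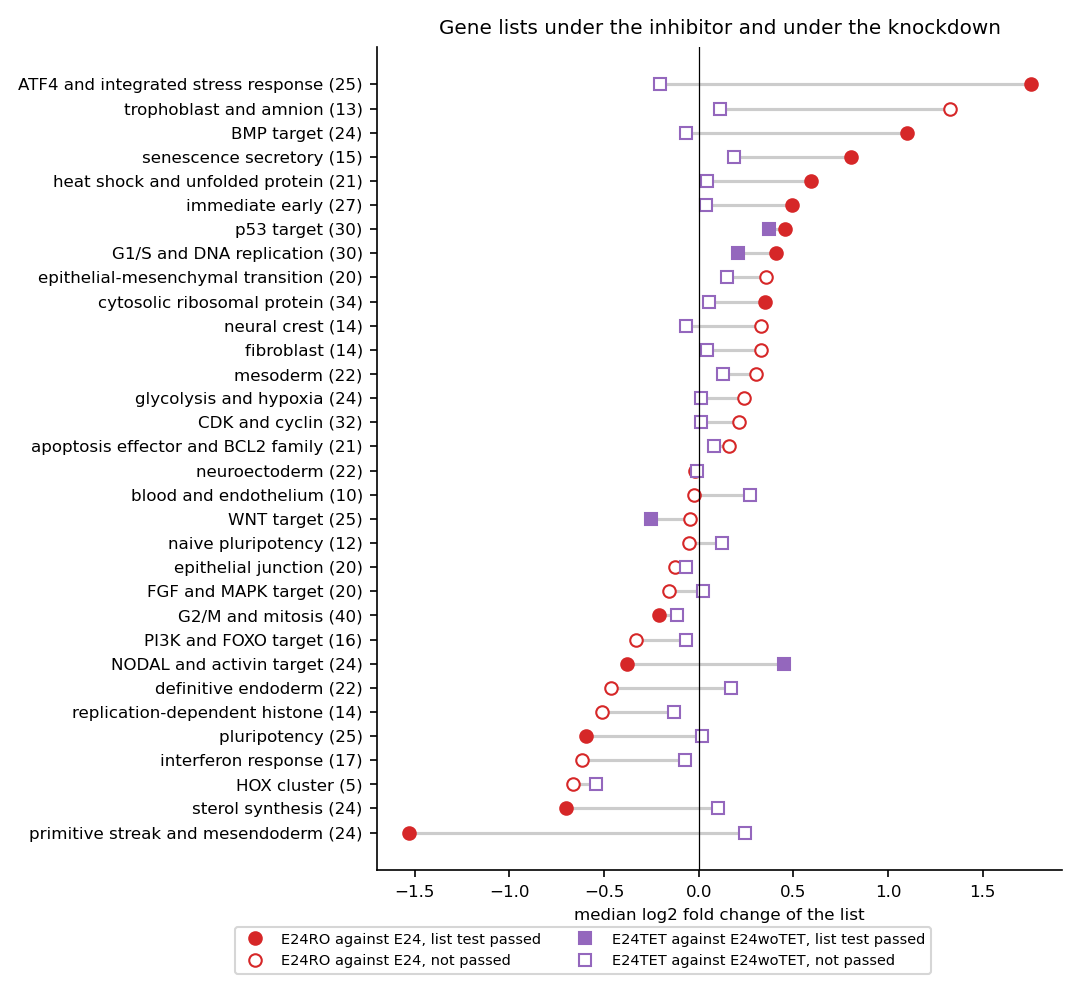
Median log2 fold change of each fixed gene list (tested members in parentheses) with the inhibitor (circles) and with the knockdown (squares), filled where the list test with the preset correlation passed. The ATF4 list stands at 1.75 with the inhibitor and -0.21 with the knockdown, and the streak list at -1.53 and 0.24.

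Across the 15465 genes, the changes with the inhibitor and with the knockdown, which share no library, had a Pearson correlation of 0.142 and a Spearman correlation of 0.200. The Pearson correlation was 0.235 over the 10367 genes at 10 CPM or more and 0.252 over the genes called with the inhibitor. Genes are not independent replicates, so no p is given, and the Pearson value was 0.0375 without E24woTET replicate 2, 0.0465 without E24RO replicate 2 and 0.220 without E24woTET replicate 1. Of the 4341 genes changed with the inhibitor, 2909 (67.0%) had the same sign with the knockdown. The genes at an unadjusted p under 0.05 with the knockdown and those called with the inhibitor had 349 in common in the same direction, where independent lists give 168. That 168 takes every gene as equally likely to pass, whatever its level and spread. The excess alone therefore does not show a shared effect. A test of the difference between the 2 effects called 327 genes higher with the inhibitor and 346 lower. TRIB3 (4.52 ± 0.34, adjusted p = 0.00175) and MESP1 (-6.18 ± 0.62, adjusted p = 0.00402) were among them, while TBXT (-1.65 ± 0.77, adjusted p = 0.221) and MIXL1 (-2.21 ± 0.89, adjusted p = 0.165) were not.

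The shRNA line and the parental cells were compared without inhibitor or tetracycline, as E24woTET against E24. Mesoderm genes were higher in the line (4 rose and 0 fell of 22 tested members, 12 and 0 adjusted over the list alone). The calls of the members TBX6, MSGN1 and RSPO3 were lost without either E24 library or without E24woTET replicate 1. With 1 library left out their values ran from 1.77 to 2.84, 3.45 to 4.85 and 2.74 to 3.28. The call of HAND1 was lost without E24 replicate 1 or E24woTET replicate 1. The mesoderm list had a median of 1.10 (adjusted p = 1.52e-06, and adjusted p = 0.276 with an estimated correlation). Streak genes were higher too (8 rose and 0 fell of 24 tested members, 11 and 1 adjusted over the list alone). The streak list had a median of 1.04 (adjusted p = 1.44e-06, and adjusted p = 0.519 with an estimated correlation). BMP targets were higher (4 rose and 0 fell of 24 tested members, 13 and 0 adjusted over the list alone). The BMP target list had a median of 0.91 (adjusted p = 9.86e-08, and adjusted p = 0.505 with an estimated correlation). MESP1 stood at 40.5 ± 3.36 CPM beside 7.36 ± 3.99 (2.49 ± 0.32, adjusted p = 0.00355). GATA6 stood at 77.6 ± 10.8 beside 21.1 ± 6.62 (1.89 ± 0.27, adjusted p = 0.00535), and NOG (2.87 ± 0.39) and the collagen gene COL1A2 (1.61 ± 0.18) were higher as well. TBXT (0.71 ± 0.55, adjusted p = 0.494, and 0.38 without E24woTET replicate 1), MIXL1 (1.00 ± 0.63, adjusted p = 0.397, on the long arm of chromosome 1), SOX2 (-0.15 ± 0.28, adjusted p = 0.807) and CDK1 (-0.15 ± 0.14, adjusted p = 0.571) did not pass. The BMP list's median was 0.47 without E24woTET replicate 1. ATF4 genes were lower (0 rose and 3 fell of 25 tested members, 0 and 8 adjusted over the list alone), among them ATF4 itself (-1.21 ± 0.17, adjusted p = 0.00500). The ATF4 list had a median of -0.58 (adjusted p = 1.52e-06, and adjusted p = 0.526 with an estimated correlation), and of -0.33 without E24woTET replicate 2.

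Several genes had few or no counts in E24 and were expressed in the line, or the reverse. Levels in UD were 35.6 CPM for CBR1, 10.1 for HDX and 6.12 for TUSC1. CBR1, a carbonyl reductase gene, had 1 count over both E24 libraries and 2060 in E24woTET, a ratio of 1785 with a 95% counting interval of 320 to 70554. PUS7L was at least 159-fold, CHMP4C at least 145-fold, HDX at least 135-fold and TUSC1 at least 94.2-fold higher in the line, taking a floor of 3 counts over the group for E24. CFLAR, which encodes an inhibitor of death receptor signalling, was higher (5.17 ± 0.31, adjusted p = 3.34e-05). In the other direction, ZNF502 had 1 count in E24woTET and 464 in E24 (ratio 535, 95.6 to 21191), and ZNF596, in the first 13 Mb of chromosome 8, 1 and 465 (ratio 537, 95.8 to 21236). ZNF717 (-5.69 ± 0.53) and CCDC152 (-5.16 ± 0.28) were lower.

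In total 398 genes were higher and 283 lower in the line, 187 and 158 of them by at least 2-fold. Of the 398, 176 (44.2%) lie on the long arm of chromosome 1, where 675 (4.36%) of the tested genes lie. The arm was chosen after its values were seen, and neighbouring genes are not independent, so no p is given. The median log2 fold change of its 600 protein-coding genes was 0.55, that of the short arm -0.01, and that of 30 genes in the first 13 Mb of chromosome 8 -1.03. With 1 library left out, 138 genes were higher and 114 lower (E24 replicate 1), 99 and 61 (E24 replicate 2), 98 and 36 (E24woTET replicate 1) or 200 and 78 (E24woTET replicate 2).

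**Figure D4:**
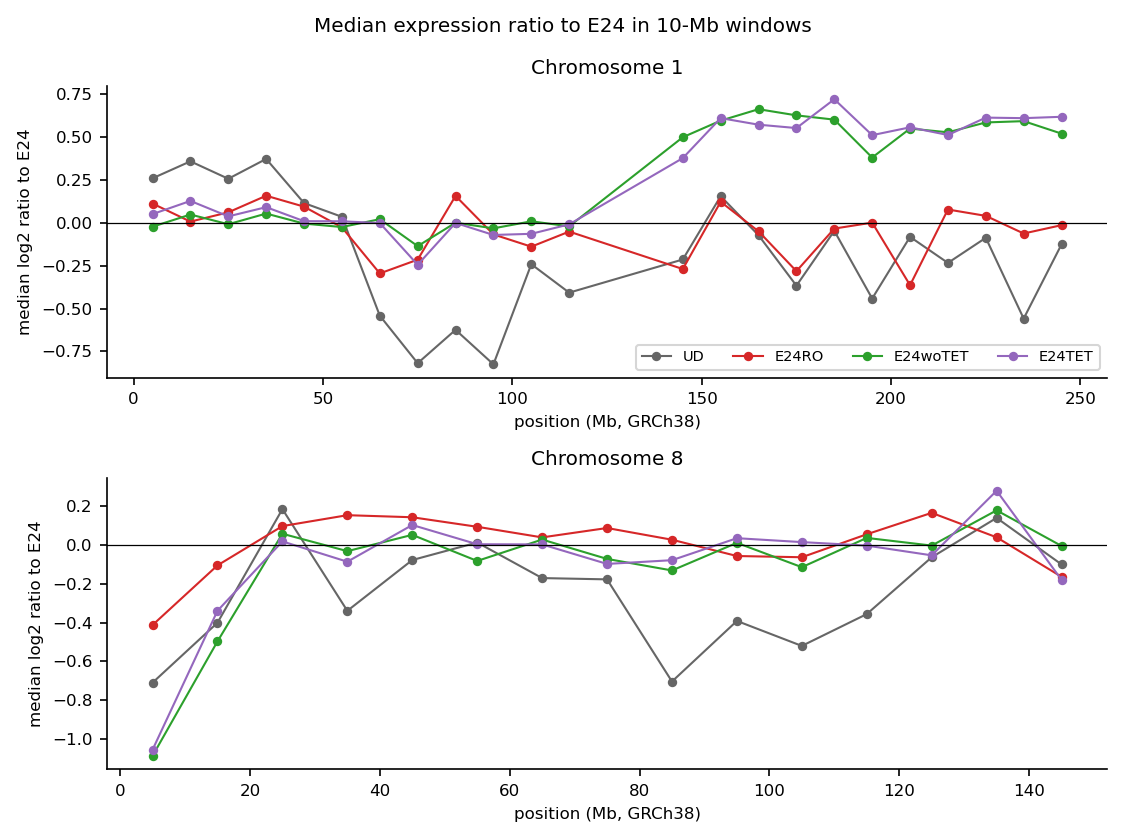
Median log2 expression ratio to E24 (vertical axis) in 10-Mb windows along chromosomes 1 and 8 (horizontal axis, Mb), by group. E24woTET and E24TET lie above the other groups along the long arm of chromosome 1, where the E24woTET median is 0.55, and below E24 at the start of chromosome 8.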

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

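The test of the inhibitor effect against the knockdown effect was planned, while the 3 tests that weigh the ATF4 pattern were chosen only after the result was seen. The results in this part were picked out because the change with the inhibitor (E24RO against E24) and the change with the knockdown (E24TET against E24woTET) differed by a test of the difference itself. Values are the inhibitor's log2 fold change minus the knockdown's. By edgeR 327 genes were higher and 346 lower, and DESeq2 called 920 and 915.

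Stress genes were higher with the inhibitor: TRIB3 by 4.52 ± 0.34, DDIT4 by 4.49 ± 0.42, CEBPB by 2.20 ± 0.23, SESN2 by 2.57 ± 0.31, HERPUD1 by 2.66 ± 0.33 and GDF15 by 2.88 ± 0.66. Mesendoderm genes were lower, with differences of -6.18 ± 0.62 for MESP1, -5.86 ± 0.97 for GSC, -4.09 ± 0.42 for GATA6, -3.36 ± 0.30 for KDR, -3.92 ± 0.78 for APLNR and -5.31 ± 1.01 for DKK4. Sterol genes were lower too, at -1.22 ± 0.17 for FDFT1 and -1.29 ± 0.21 for HMGCS1. The difference was 3.06 ± 0.52 for NOG, 1.61 ± 0.26 for ID4 and 2.79 ± 0.66 for TFAP2A. It was 1.33 ± 0.20 for CDK1, -1.13 ± 0.20 for BUB1 and -1.17 ± 0.17 for SP8. TRIB3, DDIT4, CEBPB, SESN2, HERPUD1, MESP1, GATA6 and KDR passed in each fit that left out 1 library. Without E24woTET replicate 1 the calls of GDF15, APLNR, DKK4, FDFT1, HMGCS1, NOG, ID4, TFAP2A, BUB1 and SP8 were lost (adjusted p from 0.0536 for FDFT1 to 0.154 for TFAP2A). GSC was lost without E24RO replicate 2 (adjusted p = 0.0709) and CDK1 without E24TET replicate 2 (adjusted p = 0.0507). GDF15 was lost in all but 2 of the 8 such fits. TFAP2A was also lost without either E24 library, E24RO replicate 2 or either E24TET library. APLNR was also lost without either E24 library, E24RO replicate 2 or E24TET replicate 2. DKK4, HMGCS1, ID4, NOG and BUB1 were also lost without E24 replicate 2 or E24TET replicate 2. DKK4 and NOG were lost without E24RO replicate 2 too, as were NOG, ID4 and BUB1 without E24TET replicate 1. With the replicate block the calls of GDF15 (adjusted p = 0.0700), APLNR (0.0544) and DKK4 (0.0509) were lost.

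By list, the streak and mesendoderm median differed by -1.50 (0 rose and 6 fell of 24 tested members, 0 and 8 adjusted over the list alone, adjusted p = 5.87e-08, and adjusted p = 0.496 with an estimated correlation). NODAL and activin targets (-0.87, 0 rose and 4 fell of 24 tested members, 1 and 8 adjusted over the list alone, adjusted p = 0.000159) and sterol synthesis genes (-0.65, 0 rose and 5 fell of 24 tested members, 0 and 9 adjusted over the list alone, adjusted p = 3.45e-08) were also lower, both at adjusted p = 0.496 with an estimated correlation. Pluripotency (-0.47, adjusted p = 0.00402) and definitive endoderm genes (-0.63, adjusted p = 0.0322) were lower, both at adjusted p = 0.621 with an estimated correlation. The pluripotency median was -0.27 without E24TET replicate 1. The endoderm median was 0.11 without E24TET replicate 2, -0.31 without E24woTET replicate 1, -1.08 without E24woTET replicate 2 and -1.07 without E24TET replicate 1, and its call was also lost without E24woTET replicate 1 or either E24RO library. BMP targets (1.03, 3 rose and 0 fell of 24 tested members, 8 and 0 adjusted over the list alone, adjusted p = 2.5e-05), senescence secretory genes (0.95, adjusted p = 0.00489), heat shock and unfolded protein genes (0.33, adjusted p = 0.00213) and immediate early genes (0.27, adjusted p = 0.0171) were higher, each at adjusted p = 0.496 with an estimated correlation. The senescence call was lost without E24RO replicate 2 (adjusted p = 0.0718), as was the immediate early call (adjusted p = 0.0741), which was also lost without E24 replicate 1 or E24TET replicate 1. The immediate early median was 0.15 without E24RO replicate 2, 0.46 without E24RO replicate 1 and 0.46 without E24TET replicate 2. The heat shock median was 0.14 without E24woTET replicate 1. Cytosolic ribosomal protein genes were higher by 0.31 (adjusted p = 0.00199, and adjusted p = 0.872 with an estimated correlation), a call lost without E24RO replicate 1 (median 0.16, adjusted p = 0.0714).

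The ATF4 list had the largest list difference, 2.08 (17 rose and 0 fell of 25 tested members, 24 and 0 adjusted over the list alone, adjusted p = 1.28e-39, and adjusted p = 0.260 with an estimated correlation). A weaker form of the inhibitor's effect would put the list at 0.13 with the knockdown. That product is its 1.75 with the inhibitor times a slope of 0.0753 over 4318 other genes. The measured median was -0.21, with 5 of 25 members above 0, and lay under the product in each fit that left out 1 library. Over these fits the product ran from 0.034 to 0.244 and the median from -0.40 to 0.0699. The members move together (estimated correlation 0.45) and the fits share libraries, so a weaker form is not excluded. A lower starting level in E24 than in the shRNA line is argued against by the median in E24woTET against E24, -0.58, since the line began lower, and GC content by the median of 1.80 with the GC trend taken out. An effect of the compound that does not run through CDK1 stays open as well. So does an effect of full loss of CDK1 activity that a partial loss of its mRNA does not reach. Neither was tested here, as no group received an inactive compound. The 2 interventions also differ in cell background, so the pattern may come from that as well.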

How the results depend on the processing

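The alternatives that leave out genes sharing sequence or take out a GC trend were chosen only after the data were seen, as were the chromosome regions; the others were planned. Over all alternatives, 1747 gene values kept their direction and side of the threshold, 102 lost their call, 9 gained one and 13 changed sign, none of these called in either fit. Of list values, 717 were kept, 19 lost their call, 13 gained one and 4 changed sign, 2 of which (WNT with the knockdown, definitive endoderm for inhibitor minus knockdown) were called in a fit, and the 22 region values were all kept. Sign changes without 1 library were, for E24 against UD, NANOG (-0.69 to 0.38, and 0.03 without E24 replicate 1), for E24RO against E24 NANOG (-0.72 to 0.27, and 0.19 without E24 replicate 2) and CDK1 (-0.23 to 0.14, and 0.04 without E24 replicate 2), and for E24woTET against E24 SOX2 (-0.34 to 0.0887). With the knockdown they were TBXT (-0.48 to 0.12, and 0.02 without E24TET replicate 1), POU5F1 (-0.0076 to 0.47), NANOG (-0.27 to 0.37), the ATF4 list (-0.40 to 0.0699) and the WNT list (-0.70 to 0.0053); for inhibitor minus knockdown, the definitive endoderm list (-1.08 to 0.11). CDK1 in E24RO against E24 was 0.12 with the GC trend taken out and 0.13 without genes sharing sequence as well, and the G2/M list in E24 against UD 0.0205 without genes sharing sequence. The cause of these changes was not tested. Counts moved beyond 1.5 times with DESeq2 (knockdown 42 higher and 55 lower, inhibitor minus knockdown 920 and 915, E24woTET against E24 890 and 601), and in the fit of only the groups compared (inhibitor 1077 and 1170, knockdown 0 lower), which has fewer libraries. The knockdown had 2 genes lower with no filter and 0 lower with the GC trend taken out, with or without genes sharing sequence. With 1 library left out, counts ranged over 635 to 2114 higher and 837 to 2164 lower with the inhibitor, 0 lower with the knockdown in each, 50 to 573 higher and 32 to 636 lower for inhibitor minus knockdown, 98 to 200 higher and 36 to 114 lower for E24woTET against E24, 3968 to 4201 and 3682 to 4092 for E24 against UD, and 3783 to 3900 and 3594 to 3876 for E24woTET against UD. The correlation of inhibitor and knockdown changes ranged from 0.0375 to 0.220. The replicate numbers were not taken to pair the samples: correlations of replicate differences between groups ran from -0.02 to 0.27, over only 2 numbers. The highest were 0.27 for E24woTET with E24TET and 0.24 for E24 with E24RO, groups that were compared with each other. With 2 replicate numbers, a shared batch was neither shown nor excluded. With the replicate block, the knockdown had 4 genes lower, inhibitor minus knockdown 567 higher and 658 lower, and E24woTET against E24 439 lower. Depth limits low genes most, with 17.3 M counts in E24 replicate 2. Genes with 0 counts in a group are given as bounds only, and those with 1 to 3 counts as ratios with counting intervals.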

Other observations

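All tests in this part on chromosome arms, shared sequence and silent genes were chosen only after the result was seen; the median per whole chromosome was planned.

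With the inhibitor, genes of secreted factors and of a cell cycle inhibitor rose. LTA, which encodes lymphotoxin alpha, went from 0.181 ± 0.0197 to 12.1 ± 1.68 CPM (6.01 ± 0.43, adjusted p = 0.000166), and PTHLH, a parathyroid hormone-like factor gene, from 0.362 ± 0.275 to 22.7 ± 18.3 CPM (5.81 ± 0.73, adjusted p = 0.00129). CDKN2B, a CDK4 and CDK6 inhibitor gene, rose by 3.58 ± 0.57. Of the senescence secretory list, 6 rose and 0 fell of 15 tested members (6 and 0 adjusted over the list alone). The senescence list had a median of 0.80 (adjusted p = 0.00204, and adjusted p = 0.387 with an estimated correlation), and of 0.50 with no filter on low counts and 0.45 with DESeq2. Immediate early genes were higher (9 rose and 1 fell of 27 tested members, 9 and 1 adjusted over the list alone). The immediate early list had a median of 0.49 (adjusted p = 0.00204, and adjusted p = 0.387 with an estimated correlation). It was 0.29 without E24 replicate 1, 0.77 without E24 replicate 2 and 0.28 without E24RO replicate 2.

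In the shRNA line without tetracycline, the trophoblast and amnion list was higher than in E24 (2 rose and 0 fell of 13 tested members, 2 and 0 adjusted over the list alone). The trophoblast and amnion list had a median of 1.39 (adjusted p = 0.00300, and adjusted p = 0.276 with an estimated correlation). It was 0.68 without E24woTET replicate 1 and 0.69 without E24woTET replicate 2, and the call was lost without E24 replicate 1 (adjusted p = 0.0594). HAND1, a factor of extraembryonic mesoderm and amnion, had 3 counts over both E24 libraries and 64 in E24woTET, a ratio of 18.5 with a 95% counting interval of 6.05 to 92.0. Its call was lost without E24 replicate 1 (adjusted p = 0.0816) and without E24woTET replicate 1 (adjusted p = 0.0534). Sterol synthesis genes had a higher median in the line (0.47, adjusted p = 0.000102, and adjusted p = 0.526 with an estimated correlation). So did WNT targets (0.53, adjusted p = 0.000621, and adjusted p = 0.528 with an estimated correlation). Heat shock genes (0.45, adjusted p = 0.000329, and adjusted p = 0.526 with an estimated correlation) stood at 0.22 without E24woTET replicate 1. Fibroblast genes (0.46, adjusted p = 0.000557, and adjusted p = 0.519 with an estimated correlation) stood at 0.26 without E24woTET replicate 2.

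Genes of the long arm of chromosome 1 were higher in both groups of the shRNA line. A hypothesis is an extra copy of that arm in the line, for which 3 copies in place of 2 give a log2 ratio of 0.58. In E24TET against E24RO, libraries not used to find the pattern, the median was 0.59, while it was 0.00 between the 2 groups of the line; by library against the E24 mean it was 0.56 and 0.60 in E24woTET, 0.57 and 0.63 in E24TET, -0.07 and 0.01 in E24RO and -0.12 and -0.14 in UD. GC content is argued against by a median of 0.56 with the GC trend taken out. The median of the whole chromosome was 0.18 (adjusted p = 4.71e-07), the copy number itself was not measured, and the report's counts for E24woTET against E24 may in part reflect it.

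At the start of chromosome 8 a loss of 1 of 2 copies in the line would give -1. The first 13 Mb had a median of -1.03 in E24woTET against E24 (28 of 30 genes below 0) and of -0.71 in E24TET against E24RO, and the rest of the chromosome of -0.00. UD, which is not labelled as the line, stood at -0.69 and -0.71 against the E24 mean over 21 genes. E24RO stood at -0.44 and -0.16, so a loss confined to the line may be only part of the pattern.

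Genes near-identical to another gene were lower in UD. A candidate explanation is that reads shared between copies were assigned differently in the UD libraries: the 123 genes sharing over 80% of their 50-mers had a median log2 fold change of 5.27 in E24 against UD and 5.02 in E24woTET against UD, but -0.14 in E24RO against E24, -0.09 in E24TET against E24woTET and -0.27 in E24woTET against E24. They took 26707 and 33707 counts in the UD libraries, 0.0389% of all counts in UD replicate 1, and 0.774% to 1.17% of the counts in the 24 h libraries. The GC trend of UD is argued against by a median of 5.43 with that trend taken out. Read processing of single libraries was not analysed here, so a biological difference between UD and the 24 h groups was not tested.

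Protein-coding genes sharing at most 5% of their 50-mers and with at least 5 CPM in UD were considered. Of 46 such genes called and at least 32-fold lower in E24 than in UD, 14 were within 4-fold of UD in E24woTET. They are PXMP4, HENMT1, HDX, ZSCAN1, IAH1, TUSC1, LCN9, IRAK4, DYNLT3, PUS7L, TSPYL5, CBR1, CFLAR and ZC3HAV1L, chosen after their values were seen. Their median level was 8.53 CPM in UD, 0.0278 in E24, 0 in E24RO, 8.44 in E24woTET and 7.29 in E24TET. Whether UD and E24 differ in origin was not tested. CBR1 had 4973 counts over both UD libraries and 1 in E24, a ratio of 1906 with a 95% counting interval of 342 to 75311, and PUS7L was at least 266-fold and HDX at least 183-fold lower in E24.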
